A study of Mus musculus with 8 samples.

How the data were processed

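RNA was sequenced from 8 mouse libraries, 1 per group, from E14 embryonic stem cells (ESC), expanded potential stem cells (EPSC) derived from them over 5 passages, and blastoids grown from EPSC. T0901317 was given to ESC and EPSC for 3 days at a dose the labels write as 1 uM/mL, a unit that leaves the concentration unclear. The siRNA aggregates were harvested 48 hours after transfection as day 2 blastoids, and the Type I and Type III blastoids were picked on day 5. The labels call both derived from T09-treated EPSC, give no dose or duration for them, and list no T09 in the blastoid medium. Per the labels, total RNA was treated with DNase and made into libraries with a directional kit.

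The deposited table held raw counts per gene symbol for 24888 genes in 8 columns, as whole numbers, with no column that belonged to no sample, and 5090 genes were counted in no library. The submitters' processing notes name STAR, Cuffnorm, HTSeq and the mouse build mm9, and give no versions, roles, annotation or strand setting. Of the symbols, 24409 were found in the reference annotation at hand, which is of a later build, so symbols were used as deposited and no coordinates are printed. Overlapping and antisense genes may be counted together if the strand was not used, and reads of near-identical gene copies are divided in a way that is not stated. Total counts ran from 24666260 to 40781415 per library. A gene with 0 counts allows a level of up to 0.0741 to 0.114 CPM, taken as 3 counts over the TMM-scaled total of each library.

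Counts were scaled by edgeR's TMM factors. For each of 8 comparisons of 2 libraries, a log2 ratio was formed with a prior count of 2 and given a 95% exact conditional (Clopper-Pearson) interval, and a gene was counted as different when the ratio was at least 2-fold, the interval excluded a ratio of 1 and 1 of the libraries had at least 20 counts. Sequencing reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Against 0 counts a fold was computed from a floor of 3 counts in that library and is given as a lower bound. ESC and EPSC with and without T09 also entered an edgeR quasi-likelihood fit of state plus treatment, with filterByExpr, 1 residual degree of freedom and a Benjamini-Hochberg threshold of 0.05.

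Gene lists, 24 in number, were fixed before the data were examined, as were the comparisons, the rule for named genes and the alternatives. They were LXR targets, fatty acid synthesis, cholesterol synthesis and uptake, naive pluripotency, formative, 2-cell-like, trophectoderm, placental trophoblast, primitive endoderm, mesoderm, neuroectoderm, fibroblast, p53 targets, ATF4 stress, hypoxia and glycolysis, proliferation, Wnt targets, FGF and ERK targets, BMP and Nodal targets, germline genes sensitive to methylation, imprinted genes, ribosomal proteins, histones and mitochondrial genes. Of the mitochondrial list 0 members matched a symbol in the table, and a few members of other lists, Hmgcs1 among them, also had no match and were not analysed here. Each list's median log2 ratio over members with at least 20 counts was placed among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these libraries and is not a p-value. Lists share some members, such as Scd1, Scd2, Eomes, Hand1, Lef1 and Apoe.

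The genes named were, in each of the first 5 comparisons, the 8 higher and 8 lower with the counting-interval bound furthest from 0 among those with at least 50 counts in 1 library, leaving out predicted and unnamed genes. In the fits they were the 8 higher and 8 lower with the smallest p and the same sign in both pairs. Up to 4 members of each list with the largest ratio were added, with Nr1h2, Nr1h3, Abca1, Abcg1 and Srebf1 always. Further members of lists whose change passed the test are named as examples, and Pou5f1, which did not pass, is named beside them.

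Both procedures were tested on simulated data. Among 14276 genes run at the fitted biological variation, the fit recovered 93% of genes changed 2-fold and 100% of genes changed 4-fold, with 7 false calls for T09 and 9 for state. The 2-library rule recovered 100% of genes changed 4-fold, with 13 to 34 false calls from counting noise alone. Both simulations changed only well-counted genes. That of the fit changed 100 genes at each fold and gave no gene a T09 response that differed between the states. Its recovery therefore need not hold for the real T09 fit, in which 15 genes passed. Alternatives were DESeq2-type size factors, library totals, no count minimum or a minimum of 100, thresholds of 1.5-fold and 4-fold, an assumed biological variation of 0.2, prior counts of 0.5 and 10, no filter, DESeq2 on all genes with at least 1 count, and limma-voom. A contrast of the crossed libraries and DESeq2 on the genes kept by filterByExpr were chosen after the data were seen, as were the list medians of T09-treated EPSC over T09-treated ESC. The software was R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.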

Results

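RNA sequencing counts were deposited for 8 mouse libraries, 1 per group, all derived from E14 embryonic stem cells (ESC). The set held ESC and expanded potential stem cells (EPSC, ESC passaged in a cocktail of signalling inhibitors for wider developmental potential), each untreated and after 3 days with T0901317 (T09), a synthetic agonist of the liver X receptors (LXR). It also held day 2 blastoids, which are stem cell aggregates that model the blastocyst, made after transfection with an siRNA against Nr1h2 (siNr1h2) or a non-targeting siRNA (siNT). The last 2 libraries were day 5 blastoids, labelled as derived from T09-treated EPSC and picked by hand as Type I and Type III, which the sample titles shorten to Gd and Bad. Total counts were 38187665 in EPSC, 40781415 in T09-treated EPSC, 33938785 in Type III, 37181849 in Type I, 33923249 in ESC, 36835100 in T09-treated ESC, 24666260 in siNr1h2 and 36959392 in siNT. No group had a replicate, so a difference between 2 libraries carried no p-value and could not be set against culture-to-culture spread, and its 95% exact Clopper-Pearson interval covered counting error only. Levels are in CPM, the usual depth-scaled count, after TMM scaling, and ratios are on the log2 scale.

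Nr1h2, which encodes LXR beta and was the target of the siRNA, was counted at 37.7 CPM in the siNr1h2 library (35.4 to 40.1) and 53.9 in siNT (51.6 to 56.2). The knockdown library therefore held 70.0% of the siNT level (64.9 to 75.6%), a log2 ratio of -0.51. Elsewhere Nr1h2 stood at 77.5 in EPSC, 92.0 in T09-treated EPSC, 64.3 in ESC, 73.3 in T09-treated ESC, 52.7 in Type III and 52.6 in Type I. Nr1h3, which encodes LXR alpha, was near the limit of these libraries, from 0.639 CPM in Type III to 1.22 in siNr1h2, and rested on 21 to 37 counts.

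**Figure D1:**
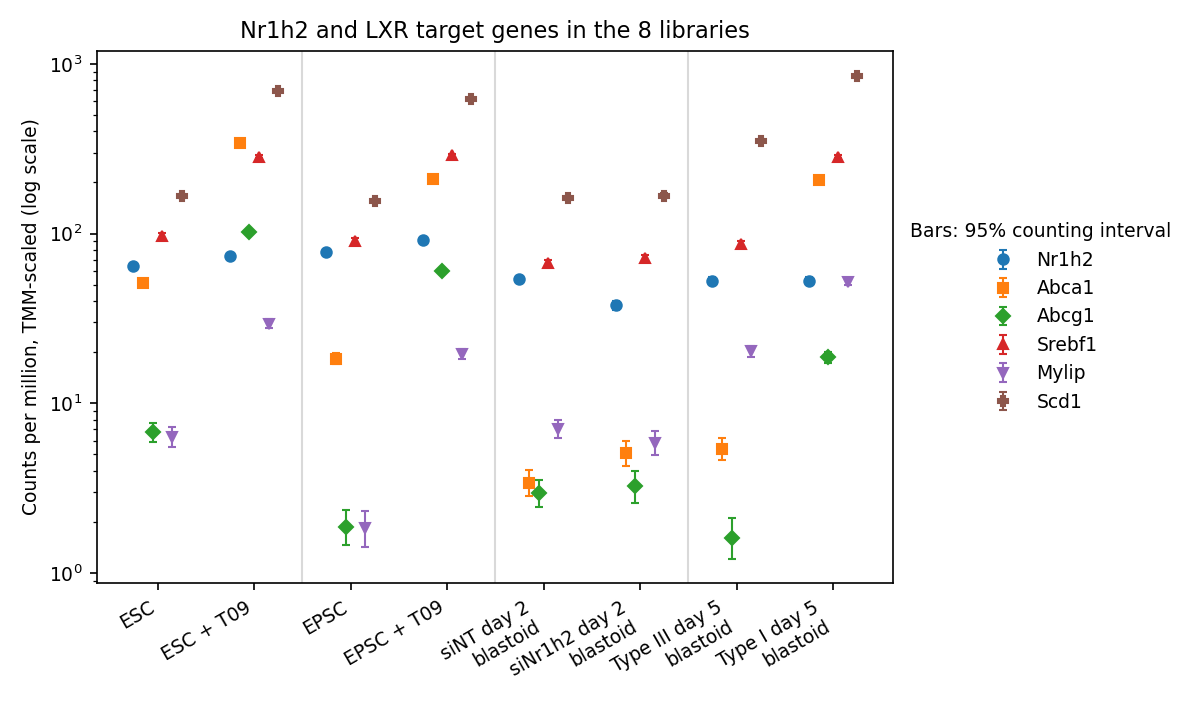
Levels of Nr1h2 and 5 LXR target genes in the 8 libraries, in CPM on a log axis, each point 1 library with its 95% counting interval. Abca1 stood at 211 in T09-treated EPSC and 207 in Type I, and at 18.3 in EPSC and 5.38 in Type III.

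The agonist libraries addressed what activation of LXR does in both stem cell states. T09 raised 7 of the 12 tested LXR targets and 4 of 16 fatty acid synthesis genes over all genes tested, each with the same sign in ESC and EPSC. Abcg1 and Abca1, the membrane transporters that export cholesterol, rose by 4.41 (SE 0.241) and 3.12 (SE 0.177) on the log2 scale over the 4 libraries. Srebf1, the transcription factor that drives fatty acid synthesis, rose by 1.61 (SE 0.104), the stearoyl-CoA desaturase genes Scd1 and Scd2 rose by 2.03 (SE 0.107) and 1.53 (SE 0.113), Mylip, the ligase that degrades the LDL receptor, rose by 2.75 (SE 0.268), and Lpcat3, which remodels membrane phospholipids, rose by 0.96 (SE 0.104). By edgeR's quasi-likelihood test on state plus treatment, 15 of 14477 genes passed a Benjamini-Hochberg adjusted p under 0.05, 13 higher and 2 lower, and 879 had an unadjusted p under 0.05. In that edgeR quasi-likelihood test the Benjamini-Hochberg adjusted p was 7.43e-05 for Scd1, Abcg1 and Abca1, 0.000194 for Srebf1, 0.000491 for Scd2, 0.00479 for Mylip and 0.0103 for Lpcat3, and each gene had the same sign in both states. Rnf145, a ubiquitin ligase gene, rose by 0.91, and Calcoco2, an autophagy receptor gene, and Ttn, which encodes titin, fell, with log2 changes of -0.85 and -0.78. The other 5 genes that passed were Acaca and Fasn, which encode the central enzymes of fatty acid synthesis (0.85 and 0.81), and Trh, Acsl3 and Bmp4 (0.83, 0.82 and 0.97), the last 3 outside the naming rule and chosen after their values were seen. The Scd genes resemble one another in sequence, so the share of counts given to each is uncertain.

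Among the gene lists fixed in advance, 7 of the 12 tested LXR targets rose over all genes tested and 9 when adjusted over the list alone, and none fell. Of 16 fatty acid synthesis genes, 4 rose over all genes and 9 rose when adjusted over the list alone. Cholesterol synthesis and uptake, the pathway that supplies sterol, had 0 of 24 genes past the test over all genes and 1 higher adjusted over the list alone. None of the 20 naive pluripotency genes passed either way. For the 21 primitive endoderm genes, which mark the extraembryonic endoderm of the blastocyst, the counts were 0 over all genes, and 1 higher with 6 lower adjusted over the list alone. Also 0 over all genes, the lists gave, adjusted over the list alone, 2 lower of 20 trophectoderm genes, 2 higher and 1 lower of 13 BMP and Nodal targets, 1 higher and 1 lower of 10 formative genes, and 1 higher and 1 lower of 10 placental trophoblast genes. Adjusted over the list alone, 1 gene was lower among 8 fibroblast genes, 17 p53 targets, 13 Wnt targets and 19 imprinted genes each, and 1 was higher among 15 hypoxia and glycolysis genes and 11 FGF and ERK targets each. The 2-cell-like, mesoderm, neuroectoderm, ATF4 stress, proliferation, germline, ribosomal protein and histone lists had 0 both over all genes and adjusted over the list alone. The count of 15 was the same with RLE size factors and with limma-voom, which shared 15 and 14 of the genes, but was 46 without a filter on low counts (23 higher and 23 lower) and 35 with DESeq2 run without that filter (19 and 16). DESeq2 on the filtered genes, an alternative chosen after the data were seen, gave 37. This fit had 1 residual degree of freedom, in which a difference between the states and the noise of a library are not separable, and ESC and EPSC are 2 states of 1 line rather than repeat cultures.

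**Figure D2:**
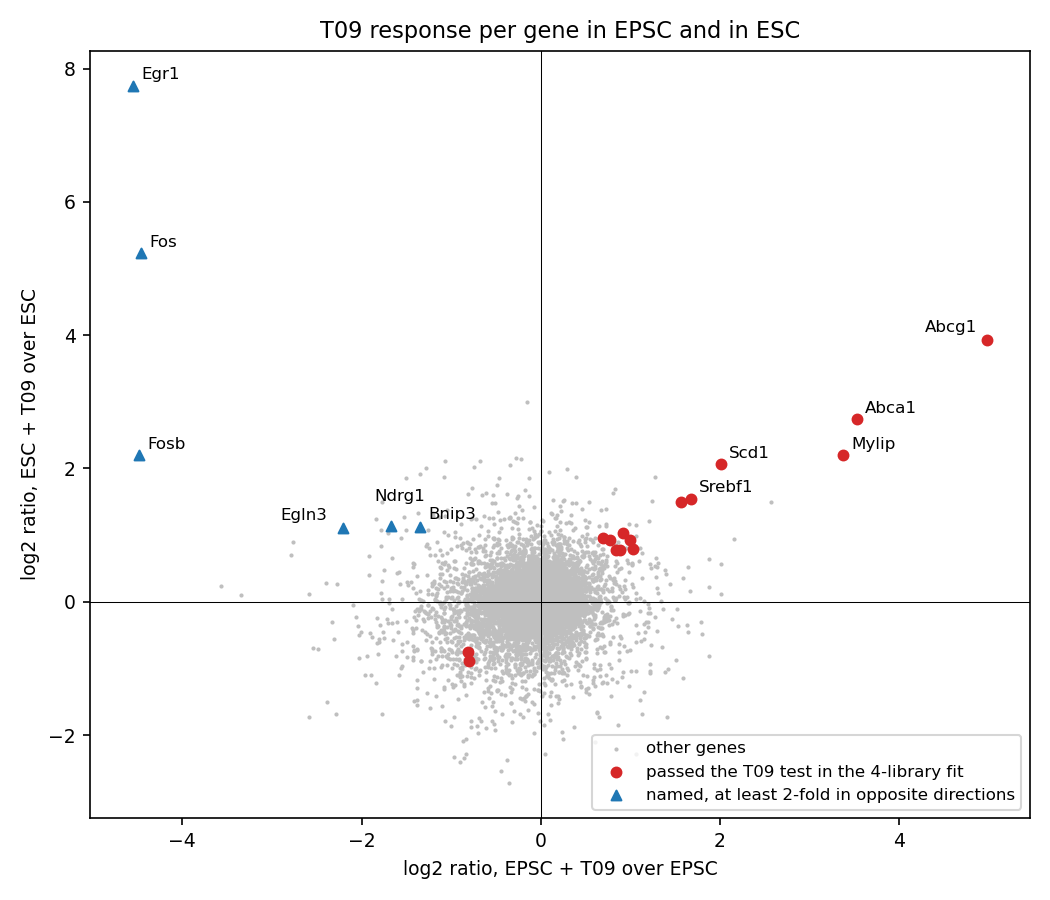
Log2 ratio of T09-treated to untreated in EPSC (horizontal axis) and in ESC (vertical axis), each point 1 gene. Abcg1 (4.98 and 3.92) and Abca1 (3.52 and 2.74) were higher with T09 in both states, and Egr1 (-4.55 and 7.74) lay on opposite sides of 0.

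In EPSC alone, the genes furthest above the untreated library were Abcg1 (60.2 against 1.86 CPM, log2 4.98), Abca1 (211 against 18.3, log2 3.52) and Mylip (log2 3.37), followed by Scd3 (2.57), Scd1 (2.01), Srebf1 (1.67), Scd2 (1.57) and Socs3, a feedback inhibitor of LIF signalling (1.38). The genes furthest below were immediate-early transcription factors and genes of other kinds. Egr1 was at 3.04 CPM with T09 and 72.2 without (-4.55), Fos at 1.26 and 28.7 (-4.45), and Fosb at -4.48. Egr2 had 0 counts with T09 and 50 without, at least 17.7-fold lower. Snap25 (1 against 95 counts, log2 -5.07, interval -11.97 to -4.14), Slc1a2 (2 against 75 counts, -4.33, interval -8.38 to -3.41) and Cplx2 (-3.34), genes of synapses and glutamate transport, were also lower, as was Adm, the hypoxia-induced gene of adrenomedullin (2 against 54 counts, -3.87, interval -7.92 to -2.92). In all, 571 of 13632 genes differed at least 2-fold, 122 higher and 449 lower with T09, and 74.6% of them had under 100 counts.

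By list, 7 of 12 LXR targets were at least 2-fold higher in T09-treated EPSC, with a median log2 ratio of 1.28 at percentile 100 of 10000 random lists matched on expression. That median was 0.79 when members with under 20 counts were kept. The fatty acid median was 0.28 (percentile 100) and the cholesterol median -0.04 (percentile 8.15). Primitive endoderm genes had a median of -0.64 (percentile 0), with the receptor gene Lrp2 at 113 against 217 CPM (-0.94) and Pdgfra at 2.32 against 4.74 (-1.01). Fibroblast genes had a median of -0.97 over 7 members (Acta2 -1.60, Col1a1 -1.02), trophectoderm genes -0.28 (Tspan8 -2.12, Gata2 1.02), imprinted genes -0.25 (Igf2 -1.26, Mirg 1.08) and hypoxia genes -0.28, with Egln3 at -2.21, Ndrg1 at -1.67 and Bnip3 at -1.35. Naive pluripotency genes had a median of 0.13, no member reaching 2-fold, and FGF and ERK targets 0.18 (percentile 98.9). The 6 neuroectoderm genes had a median of -0.03 (percentile 46.5), and 19 of 20 ribosomal protein genes were above 0, with a median of 0.11 (percentile 96.6).

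In ESC alone, the LXR targets again stood out, with Abcg1 at 103 against 6.72 CPM (3.92), Abca1 at 340 against 51.0 (2.74), Mylip at 29.4 against 6.36 (2.20) and Scd1 at 694 against 166 (2.06). Egr1 (89.9 against 0.362 CPM, 7.74) and Fos (22.5 against 0.542, 5.23) were higher with T09 here. Slfn9 (1.95) and Slc22a18 (2.51) were higher too. The genes furthest below the untreated library were Mical2 (-2.53), the trophectoderm factor Gata3 (0.614 against 3.23 CPM, -2.29), Pramel7 (-2.05), the glucose transporter gene Slc5a1 (-1.89), the imprinted gene Dlk1 (-1.86), Mttp, which loads lipid onto lipoproteins (-1.79), the meiotic cohesin gene Smc1b (-1.74) and Fam198b (-1.56). In all, 525 of 13412 genes differed at least 2-fold, 186 higher and 339 lower, and 76.4% of them had under 100 counts.

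The LXR median in ESC was 1.21 over 12 genes (percentile 100) and the fatty acid median 0.52 (percentile 100). The cholesterol median was 0.42 (percentile 100), with 23 of 24 cholesterol genes above 0, among them Pmvk (0.84) and Dhcr7 (0.77). Untreated EPSC over untreated ESC also had a cholesterol median above 0, at 0.34. Both ratios share the untreated ESC library, so a level particular to that library cannot be told apart from a T09 response. With T09 in ESC, hypoxia genes had a median of 0.55 (percentile 100), with Ndrg1 at 1.13, Bnip3 at 1.12 and Egln3 at 1.10. The 2-cell-like genes, a set switched on in rare stem cells that resemble the 2-cell embryo, had a median of -0.91 (percentile 0.05), with Usp17la at -1.72, Tmem92 at -1.69 and Zscan4f at -1.28. Formative genes (-0.34), primitive endoderm genes (-0.31), imprinted genes (-0.22), p53 targets (-0.17) and 6 neuroectoderm genes (-0.59) lay below 0, and trophectoderm genes (0.27), BMP and Nodal targets (0.26) and ATF4 stress genes (0.12) above. Ribosomal protein genes, a list kept as a check on library quality, lay above as well, with 19 of 20 over 0 and a median of 0.12 (percentile 99.98). The Zscan4 and Usp17l genes are near-identical copies, so the counts of a single member are uncertain. Over 12944 genes the T09 ratios in EPSC and ESC had a Pearson correlation of 0.083 and a Spearman correlation of 0.083 across genes, which are not independent replicates, and 52.2% had the same sign.

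**Figure D3:**
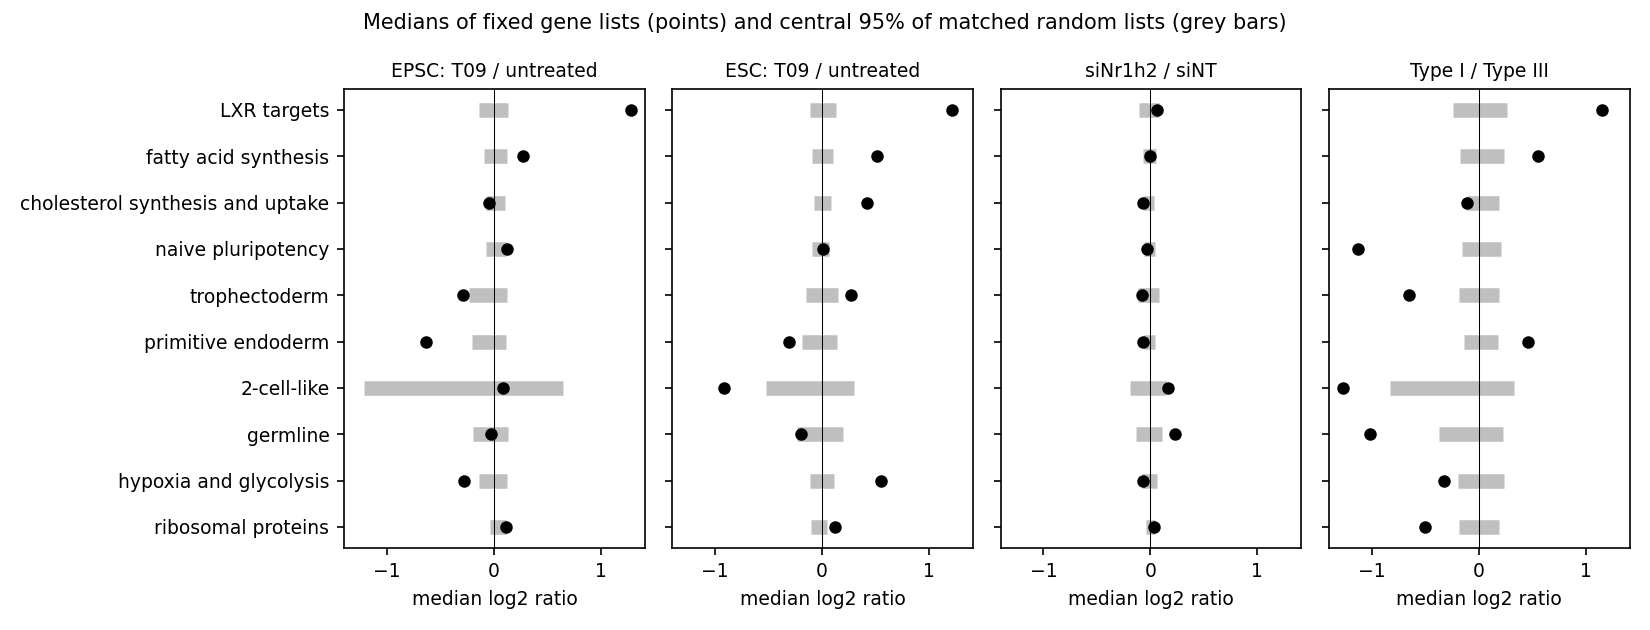
Median log2 ratio of 10 fixed gene lists (points) in 4 comparisons, with the central 95% of random lists matched on expression (grey bars). The LXR median was 1.28 and 1.21 with T09, 0.06 for siNr1h2 over siNT and 1.15 for Type I over Type III.

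The untreated ESC and EPSC, and their treated partners, addressed how the EPSC state differs from ESC. Of 13 Wnt targets 8 fell and 0 rose in EPSC over all genes tested, and of 16 germline genes 11 rose and 2 fell. In the edgeR fit over 4 libraries, Cdx1, a homeobox gene activated by Wnt, had a log2 change of -7.39 (SE 0.191), and Axin2, the feedback inhibitor of the pathway, -3.39. Sp5, a further Wnt target, had 0 counts in untreated EPSC and was at least 120-fold lower there than in ESC. Enpp3 rose by 5.41 (SE 0.175), the meiotic regulator Stra8 by 3.76 (SE 0.141), the Polycomb gene Scml2 by 4.43, the germ cell RNA-binding gene Dazl by 2.70 (SE 0.112), the fatty acid binding gene Fabp3 by 2.90, the type IV collagen genes Col4a1 and Col4a2 by 2.53 and 3.09, and Islr2 by 3.34. Further genes that fell were Dmgdh (-5.81), Dnah8 (-4.45), Nefm (-6.01), Ntn1 (-4.43), the imprinted gene Plagl1 (-3.26), Crxos (-3.02) and Tes (-4.03). By edgeR's quasi-likelihood test 4172 of 14477 genes passed a Benjamini-Hochberg adjusted p under 0.05, 2069 higher and 2103 lower in EPSC, and the adjusted p of Cdx1 was 1.52e-07. The cultures differ in serum, inhibitors and passages together, and so no single component can be held to account for a gene. Each state is 1 culture line with both of its libraries in the fit. The p-values and SEs therefore do not cover the spread between separate derivations of EPSC.

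Of 13 Wnt targets, 8 fell over all genes tested and 9 adjusted over the list alone, and 0 rose. Of the 12 tested 2-cell-like genes, 7 fell over all genes (Zscan4c -2.83) and 9 adjusted over the list alone. Of 21 primitive endoderm genes, 12 rose and 3 fell both over all genes and adjusted over the list alone, with Gata6 at 3.90, Sox7 at 4.96 and the receptor gene Cubn at 3.66. Of 16 germline genes, 11 rose and 2 fell over all genes, and 12 rose and 2 fell adjusted over the list alone, with Asz1 at 4.06 and Mael at 2.91. Of 20 naive pluripotency genes, 2 rose and 10 fell over all genes, and 3 rose and 10 fell adjusted over the list alone. Tfcp2l1 fell (-1.74), Nanog fell (-1.09) and Utf1 rose (1.88), whereas Pou5f1 had a log2 change of -0.12 with a Benjamini-Hochberg adjusted p of 0.474 in edgeR's quasi-likelihood test. Of 20 trophectoderm genes, 6 rose and 9 fell by both counts, over all genes and adjusted over the list alone, with Lgals3 at 2.18, Fgfr2 at 1.92, Eomes at -2.45 and Cdx2 at 2 counts in untreated EPSC against 72 in ESC (log2 -4.36, interval -8.45 to -3.47). Of 12 LXR targets, 3 rose and 6 fell by both counts, over all genes and adjusted over the list alone.

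For the remaining lists the counts are given over all genes and then adjusted over the list alone. Hypoxia and glycolysis genes gave 1 higher and 8 lower of 15, then 1 and 10, with lactate dehydrogenase gene Ldha at -1.94. P53 targets gave 1 higher and 6 lower of 17, then 1 and 7, with Cdkn1a at -2.08. ATF4 stress genes gave 1 higher and 4 lower of 16, then 4 and 6, with Asns at -2.20. FGF and ERK targets gave 5 higher and 3 lower of 11 both times, with Dusp6 at 2.54, and BMP and Nodal targets 3 higher and 4 lower of 13 both times, with Lefty1 at 2.28. Formative genes gave 4 higher and 1 lower of 10 both times (Otx2 2.53), and neuroectoderm genes 4 higher and 1 lower of 6, then 5 and 1 (Pax6 4.35). Mesoderm genes gave 0 higher and 5 lower of 10 both times, fibroblast genes 1 higher and 4 lower of 8 both times (Acta2 5.30), placental genes 2 higher and 3 lower of 10 both times, and fatty acid genes 1 higher and 4 lower of 16 both times. Cholesterol genes gave 3 higher and 1 lower of 24, then 2 and 1, and proliferation genes 1 higher and 5 lower of 20 both times. Imprinted genes gave 0 higher and 2 lower of 19 both times, Plagl1 and Peg10. Ribosomal protein genes gave 1 lower of 20, then 0, and histone genes 0 of 11 both times.

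Between the untreated libraries alone, 2441 of 13847 genes differed at least 2-fold, 1327 higher and 1114 lower in EPSC. The furthest above ESC were Egr1 (72.2 against 0.362 CPM, 7.44), Fos (5.59), Enpp3 (5.40), Usp26 (5.49), the smooth muscle actin gene Acta2 (5.09) and 3 genes with 0 counts in ESC, Sgcd at least 69.5-fold higher, Rgcc at least 60.2-fold and Cdk15 at least 27.8-fold. In the treated pair the first 2 went the other way, with Egr1 at 3.04 CPM in T09-treated EPSC against 89.9 in T09-treated ESC and Fos at 1.26 against 22.5. The furthest below were Cdx1 (0.445 against 87.6 CPM, -7.45), Nkx1-2 (0 counts in EPSC, at least 150-fold lower), Sp5, Dmgdh (-5.76), Nefm (-5.71), Bhmt2 (-5.51), Cd4 (-5.60) and Cnga4 (2 against 182 counts, -5.68, interval -9.77 to -4.84). Cholesterol genes had a median of 0.34 here (percentile 100), with 21 of 24 above 0, and LXR targets a median of -0.54 (percentile 0.04), with Abcg1 at -1.82, Mylip at -1.76 and Abca1 at -1.48. Some medians depended on the pair, as a look at T09-treated EPSC over T09-treated ESC showed, which was chosen after the data were seen. Cholesterol genes had a median of -0.10 there, and trophectoderm genes -1.14, with 4 at least 2-fold higher and 10 lower, against 0.41 (percentile 98.4), with 5 higher and 4 lower, in the untreated pair. Hypoxia genes stood at -1.41 against -0.22, and FGF and ERK targets at -0.01 against 0.70. LXR targets stood at -0.26 (percentile 2.12) against -0.54, and placental genes at -0.32 against 0.50.

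The knockdown pair addressed what a lower Nr1h2 level does in day 2 blastoids. None of the 12 LXR targets with enough counts differed 2-fold between siNr1h2 and siNT. Their median log2 ratio was 0.06 (percentile 93.0), with Abca1 at 5.07 against 3.40 CPM (0.57), Abcg1 at 0.13, Srebf1 at 0.09 and Mylip at -0.27. Cholesterol genes lay slightly below 0, with a median of -0.07 (percentile 0.97) and 20 of 24 members below, among them Insig1 (-0.21) and Sc5d (-0.20). Primitive endoderm genes had the same median of -0.07 (percentile 0.61), with Afp at -1.32, Apoa1 at -0.86 and Apob at -0.39, and 20 of 25 members were below 0. Germline genes had a median of 0.23 (percentile 99.97), led by Tex101 (0.92), Slc25a31 (0.78) and Sycp1 (0.63), and 2-cell-like genes 0.16 (percentile 98.4). These lay beside a histone median of 0.46 (percentile 98.0) and an Rn45s share of 0.683% in siNr1h2 against 0.220% in siNT. Naive pluripotency (-0.04) and trophectoderm (-0.08) genes lay inside the range of random lists, with no member 2-fold apart.

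The genes furthest above siNT were the ribosomal RNA precursor Rn45s (6429 against 2069 CPM, 1.64), the mitochondrial leucyl-tRNA synthetase gene Lars2 (580 against 190, 1.61), Prox1 (2.06 against 0.559, 1.77), Ptprt (1.35), Ccdc152 (1.47), Chadl (1.55), Fos (1.48) and Pde9a (1.28). The furthest below were the protease gene Prss12 (0.343 against 2.36 CPM, -2.58), Nrn1l (-2.23), Rasal3 (-2.10), Myom3 (-2.18), AI429214 (-2.06), Itih5 (-1.96), Rab36 (-1.74) and Ido1 (-1.78). Rn45s took 0.683% of the siNr1h2 counts and 0.126% to 0.220% in the other 7 libraries, so the library stood apart in its content of ribosomal RNA. Lars2 stood apart in the same library, at 580 CPM against 114 to 225 in the other 7. Whether either rise belongs to the knockdown or to the making of this library was not tested. In all, 517 of 14127 genes differed at least 2-fold, 210 higher and 307 lower, and 485 of them, 93.8%, had under 100 counts. The count minimum was set on raw counts, and siNr1h2 was the shallower library. A gene higher in siNr1h2 thus needed a higher level to be counted, so the split of higher and lower depends in part on depth. With no count minimum the number was 1134, 607 higher and 527 lower, and with a minimum of 100 counts it was 32. Over 12673 genes the siNr1h2 ratio and the mean T09 ratio had a Pearson correlation of -0.057 and a Spearman correlation of -0.082 across genes, and within the 15 genes that passed for T09 the values were 0.081 and 0.121.

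The Type I and Type III libraries compare the classes of blastoid that the submitters separated. LXR targets and the fatty acid genes were higher in Type I, and pluripotency, germline and 2-cell-like genes were higher in Type III. Abca1 stood at 207 CPM in Type I and 5.38 in Type III, a 38.4-fold ratio (log2 5.25, interval 5.05 to 5.49), and Abcg1 at 18.7 and 1.61 (3.49). Srebf1 (283 against 86.8 CPM, 1.71) and Scd2 (2546 against 852, 1.58) followed. Nr1h2 itself stood at 52.6 against 52.7. Of 13 LXR targets, 8 were at least 2-fold higher and 1 lower in Type I, with a median of 1.15 (percentile 100), and fatty acid genes had a median of 0.56 (percentile 100), with Fasn at 0.96 and Acaca at 0.87. Cholesterol genes had a median of -0.11 (percentile 2.33).

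Naive pluripotency genes were lower in Type I, 14 of 20 at least 2-fold, with a median of -1.12 (percentile 0), led by Tcl1 (-2.53), Nr0b1 (-2.23), Dppa3 (-1.76) and Dppa5a (201 against 635 CPM, -1.66). The 14 germline genes had a median of -1.01 (Hormad1 -2.18, Dazl -2.18) and the 11 measured 2-cell-like genes -1.27 (Zscan4a -2.52). Trophectoderm genes, the markers of the outer layer of the blastocyst, had a median of -0.65 (percentile 0), with Hand1 at 2.81 against 16.3 CPM (-2.51) and Anxa2 at 35.9 against 102 (-1.50), and placental genes -0.68 (Rhox9 -1.56, Synb -1.38). Mesoderm genes had a median of -0.85, BMP and Nodal targets -0.50 with Lefty2 at -3.01 and Tdgf1 at -1.91, and FGF and ERK targets -0.47. Primitive endoderm genes were higher in Type I, with a median of 0.46 (percentile 100) and 21 of 25 above 0, led by Col4a2 (1.11) and Col4a1 (1.01). ATF4 stress genes (-0.34), hypoxia genes (-0.33), all 20 ribosomal protein genes (median -0.50) and 10 histone genes (-1.17) were lower in Type I, whereas proliferation genes (0.01), p53 targets (0.09) and Wnt targets (0.18) lay within the range of random lists. Near-identical copies make the values of single Rhox, Zscan4 and histone genes uncertain.

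Beyond the lists, the genes furthest above Type III were Sema3d (2.56 against 0.335 CPM, 2.74), the B cell factor gene Pax5 (2.55), the adenylyl cyclase gene Adcy8 (2.61) and the epithelial factor gene Trp63 (2.40). The furthest below were the calcium-binding gene S100a6 (0.306 against 6.54 CPM, -4.18), Serpinb9e (-3.56), Ndufa4l2 (-3.29), Ctla2a (-3.28), Guca1a (-3.30), Pglyrp1 (-3.16), Lefty2 and the osteopontin gene Spp1 (1.37 against 9.61, -2.76). In all, 1068 of 13907 genes differed at least 2-fold, 268 higher and 800 lower in Type I, and 66.8% of them had under 100 counts. Each class was 1 library of picked structures, so the difference cannot be separated from that between single batches of blastoids.

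**Figure D4:**
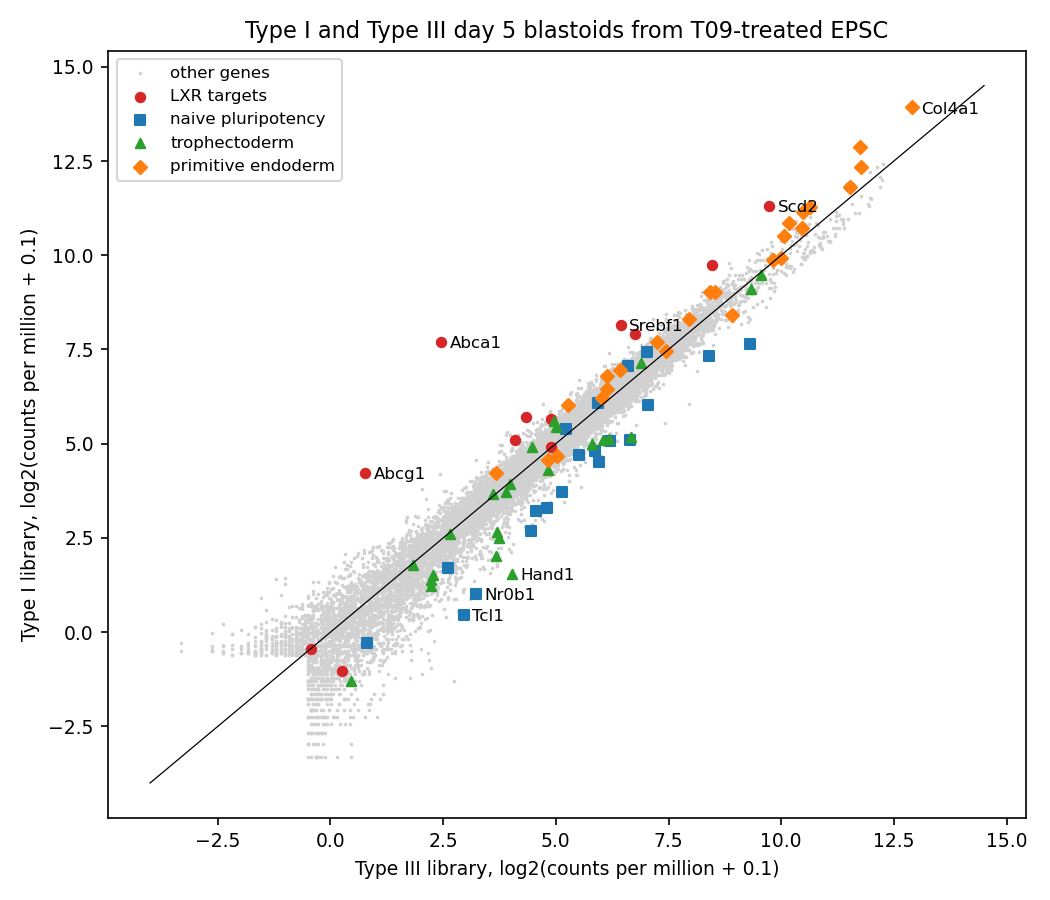
Levels in the Type III (horizontal axis) and Type I (vertical axis) libraries, log2 of CPM plus 0.1, each point 1 gene, with the line of equal level. Abca1 (207 in Type I, 5.38 in Type III) lay furthest above the line among the coloured lists, and naive pluripotency genes such as Tcl1 and Nr0b1 lay below.

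Set against untreated EPSC, the siNT library held more transcript of primitive endoderm genes and less of naive pluripotency genes. So did the Type I and Type III libraries against T09-treated EPSC. These EPSC libraries stand for the kind of cell the blastoids were seeded from, and are not known to be the same cultures. In siNT blastoids at day 2, 22 of 25 primitive endoderm genes were at least 2-fold higher than in EPSC, with a median of 3.62, and the intestinal cobalamin receptor genes Cubn (7.84) and Amn (6.93) and the lipoprotein gene Apob (7.97) led. Trophectoderm genes had a median of 1.67, with Cdx2, the lineage's founding factor, at 31.5 CPM against 2 counts in EPSC (8.24, interval 7.38 to 12.28), and Hand1 at 232 counts against 0. Mesoderm genes (3.91, with T at 5.61), Wnt targets (3.65, with Lef1 at 5.16), 2-cell-like genes (4.24, with Zscan4c at 5.28), formative genes (1.86) and imprinted genes (1.30, with H19 at 1325 against 13.7 CPM) were higher too. FGF and ERK targets had a median of 1.47, with 7 at least 2-fold higher and 3 lower. Placental genes were split, with a median of 2.29 but 6 of 11 members above 0 and 5 below. Naive pluripotency genes had a median of -0.98, with Tcl1 at -3.03 and Prdm14 at -2.87, and 6 neuroectoderm genes -1.68, with Sox1 at -3.92. The p53 targets (0.63), BMP and Nodal targets (0.34) and ribosomal protein genes (0.15) lay above 0, and proliferation genes (-0.40) below. In all, 3740 of 14496 genes differed at least 2-fold, 2107 higher and 1633 lower, with medium, transfection and time differing at once.

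Type I blastoids at day 5 held all 25 primitive endoderm genes at least 2-fold above T09-treated EPSC, with a median of 6.45. Apob was at 10.93, Cubn at 9.20 and Ttr, the transthyretin gene, at 11.16 against 1 count (interval 10.32 to 18.10). On the trophectoderm list, the keratin genes Krt18 (553 against 1.80 CPM, 8.22) and Krt8 (7.12) were higher and Aqp3 was lower (-7.06). Which cells held the keratin transcripts was not measured. The trophectoderm median was 1.95, beside 2.32 for placental genes, 3.67 for mesoderm genes and 3.54 for Wnt targets. Naive pluripotency genes had a median of -3.37, with Esrrb at 13.1 against 610 CPM (-5.53). Abca1 (207 against 211 CPM) and Srebf1 (283 against 289) stood at the level of T09-treated EPSC, whereas Abcg1 was lower (18.7 against 60.2, -1.69) and Mylip higher (52.0 against 19.5, 1.41). Of 12 LXR targets, 4 were at least 2-fold higher and 1 lower, with a median of 0.12. In all, 5868 of 14378 genes differed at least 2-fold, 3266 higher and 2602 lower.

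In Type III blastoids 24 of 25 primitive endoderm genes were at least 2-fold above T09-treated EPSC (median 6.46), trophectoderm genes had a median of 2.64 (Krt18 8.45, Krt8 7.19), and naive pluripotency genes had a median of -2.65, with Esrrb at -4.11. The LXR median was -0.82 (percentile 0.365), with Abca1 at 5.38 against 211 CPM (-5.28) and Abcg1 at 1.61 against 60.2 (-5.18), whereas Mylip was at 20.2 against 19.5 (0.05). That median was -0.20 when members with under 20 counts were kept. Fatty acid genes had a median of -0.72 (percentile 0.34), and the 11 measured 2-cell-like genes 2.77. The medians were 4.43 for mesoderm genes, 3.52 for Wnt targets, 3.18 for placental genes, 2.54 for 9 fibroblast genes, 0.92 for formative genes and 0.52 for ribosomal protein genes. In all, 5423 of 14395 genes differed at least 2-fold, 3117 higher and 2306 lower, and time and medium differ between these libraries as well.

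**Figure D5:**
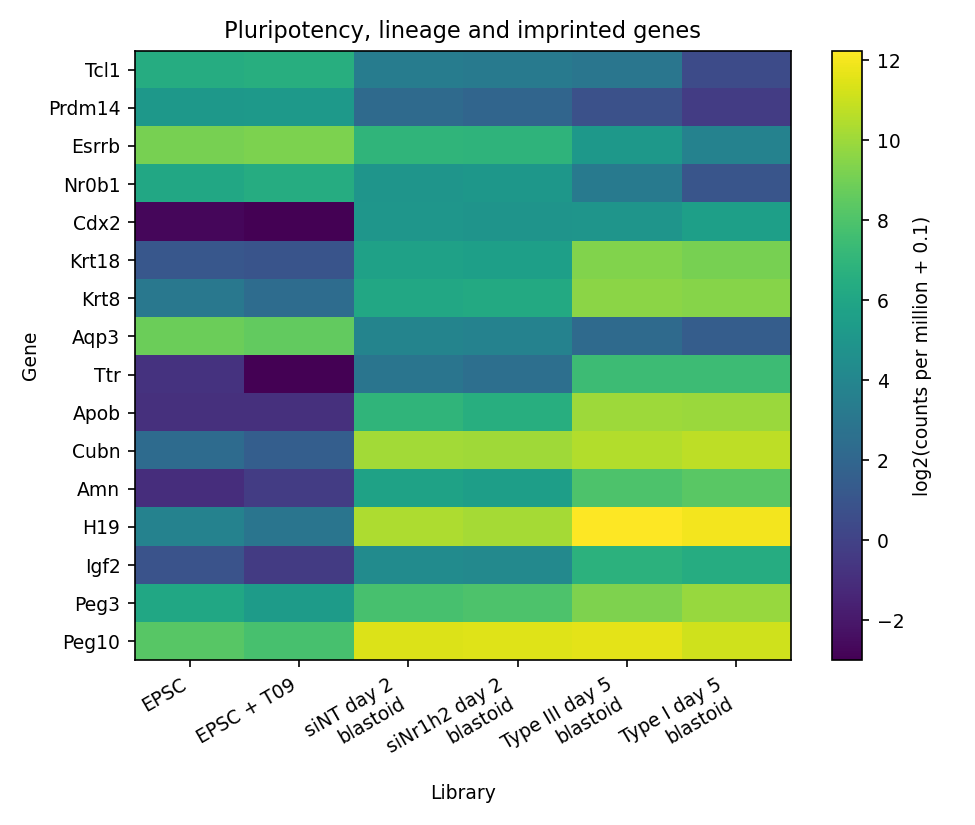
Log2 of CPM plus 0.1 for 4 naive pluripotency, 4 trophectoderm, 4 primitive endoderm and 4 imprinted genes (top to bottom) in EPSC, T09-treated EPSC and the 4 blastoid libraries, the genes chosen after their values were seen. Esrrb went from 610 CPM in T09-treated EPSC to 13.1 in Type I, and Krt18 from 1.80 to 553.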

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

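All the tests of explanations in this part, and the contrast of crossed libraries, were chosen only after the results were seen. The immediate-early genes Egr1, Fos and Fosb and the hypoxia genes Egln3, Ndrg1 and Bnip3 drew attention because T09 went with opposite directions in the 2 cell states, lower in T09-treated EPSC and higher in T09-treated ESC than in the untreated partner. Only the named genes were searched for this. Over all genes, 70 were at least 2-fold apart in both pairs. Of these, 36 went in opposite directions, 25 of them lower with T09 in EPSC and higher in ESC, and 34 went in the same direction. Of the 34, 11 were higher and the rest lower with T09. Unrelated pairs would share 1.75 higher and 11.8 lower genes by the product of their counts. No such number was computed for the opposite genes. The log2 ratio in ESC minus that in EPSC was 12.29 for Egr1 (7.74 against -4.55), 9.69 for Fos (5.23 against -4.45), 6.68 for Fosb (2.19 against -4.48), 3.31 for Egln3 (1.10 against -2.21), 2.80 for Ndrg1 (1.13 against -1.67) and 2.47 for Bnip3 (1.12 against -1.35). Against repeat cultures the difference was not tested, since each state had 1 treated and 1 untreated library. A contrast of T09-treated ESC and untreated EPSC against the other 2 libraries, with cell state as a block, leaves the T09 effect and library noise as its 1 residual degree of freedom. In it edgeR's quasi-likelihood test passed 1 gene, Fos (log2 4.86, Benjamini-Hochberg adjusted p 0.00612), while the adjusted p was 0.152 for Egr1 and Bnip3, 0.635 for Ndrg1, 0.869 for Fosb and 1.00 for Egln3. That contrast had 421 genes at an unadjusted p under 0.05, and passed 1 gene with RLE size factors, 1 with limma-voom, 19 without a filter and 11 with DESeq2, whether or not the filter was applied.

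Exchanged labels within 1 of the pairs are argued against by the LXR targets, whose median was higher with T09 in both, the smaller being 1.21. Unequal inhibition of MEK is argued against by the ERK feedback genes Dusp4, Dusp6, Spry2, Spry4, Spred1, Etv4 and Etv5, whose median difference between the states was -0.32 with values from -0.66 to 0.36. Of the 15 hypoxia genes measured in both pairs, 10 were lower with T09 in EPSC and higher in ESC. A difference between cultures apart from the agonist, such as density, oxygen or handling at harvest, therefore cannot be told apart from a response to T09 that depends on cell state, because no culture was repeated.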

How the results depend on the processing

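The contrast of crossed libraries and DESeq2 on the filtered genes were chosen after the data were seen. Of 76 recomputed values that answer a comparison, 49 stayed close and 27 moved. The counts of genes at least 2-fold apart moved with the thresholds that define them. With no count minimum they were 1134 for siNr1h2 over siNT (607 higher and 527 lower, so the larger share turned over), 1045 for T09 in EPSC, 913 for T09 in ESC and 1761 for Type I over Type III. With a minimum of 100 counts they were 32, 145 and 124 for the first 3 of these, 1424 for EPSC over ESC, 355 for Type I over Type III and 2394 for siNT over EPSC. At 1.5-fold they were 1048 for siNr1h2, 1374 and 1293 for T09 in EPSC and ESC, 4143 for EPSC over ESC, 2307 for Type I over Type III and 5799 for siNT over EPSC. At 4-fold they were 84 for siNr1h2, 84 and 51 for T09 in EPSC and ESC, 859 for EPSC over ESC, 153 for Type I over Type III, 1609 for siNT over EPSC, and 3114 and 2693 for Type I and Type III over T09-treated EPSC. A looser or stricter threshold counts more or fewer genes by construction. The 15 genes of the T09 fit became 46 without a filter (23 higher and 23 lower), 35 with DESeq2 run without that filter (19 and 16) and 37 with DESeq2 on the filtered genes (20 and 17). All 3 held the 15, so for DESeq2 the filter does not account for the change. The state fit passed 4164 genes with RLE size factors, 4294 without a filter, 3119 with DESeq2, 3151 with DESeq2 on the filtered genes and 4284 with limma-voom. With an assumed biological variation of 0.2 the siNr1h2 count was 445, T09 in EPSC 510 and T09 in ESC 448. Other scalings shifted the median of all genes by at most 0.0906 on the log2 scale, and Nr1h2 in the knockdown stayed between -0.50 and -0.52. Of 736 recomputed list medians 7 moved, and 10 medians close to 0 changed sign with the scaling, so no direction is given for those. Of 2391 recomputed values of named genes 167 moved. Leaving out 1 cell state from the T09 fit leaves 2 libraries and no test, so its values are the ratios of each pair. Depth limits most the genes with under 100 counts, which made up 93.8% of those called for siNr1h2 and 27.0% for Type I over T09-treated EPSC.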

Other observations

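The tests of explanations in the last 2 paragraphs were chosen only after the results were seen, and the gene lists were fixed beforehand. From T09-treated EPSC to day 5 blastoids, germline genes had a median log2 ratio of -1.85 in Type I and -0.97 in Type III. Of 16 members, 11 were at least 2-fold lower and 1 higher in Type I, and 7 were lower and 4 higher in Type III. Dazl, an RNA-binding gene of germ cells, stood at 159 CPM in the EPSC, 4.38 in Type III and 0.919 in Type I. Imprinted genes were higher in both, with medians of 2.57 and 2.48. H19, a growth-restraining RNA, stood at 7.34 in the EPSC, 4828 in Type III and 4068 in Type I, and Igf2, its neighbour that encodes a growth factor, at 0.692, 111 and 86.8. Hypoxia and glycolysis genes had medians of 1.52 in Type I and 1.58 in Type III, with Bnip3 at 4.45 and 4.73. The p53 targets had medians of 0.96 and 1.01, with the cell cycle inhibitor gene Cdkn1a at 2.20 and 1.80, and proliferation genes -0.65 and -0.67, with the replication gene Mcm2 at -1.59 and -1.66.

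The Nodal targets Lefty1 (-7.42 and -5.81) and Lefty2 (-6.84 and -3.82) were lower in Type I and Type III than in T09-treated EPSC, and the BMP target Id2 was higher (5.02 and 4.75), but the list of 13 BMP and Nodal targets had 7 above and 6 below 0 in both comparisons, its medians of 0.32 and 0.45 inside the range of random lists. In siNT day 2 blastoids Lefty1 was also below EPSC (-6.62), and Id3 (5.70) and Id1 (4.98) were above. The placental genes Flt1, a receptor of VEGF, and Cited1 were at 9.93 and 9.12 in Type I and 9.14 and 8.72 in Type III, and Synb, which encodes a protein of cell fusion, was at least 56.2-fold higher in Type III against 0 counts in T09-treated EPSC. Among sterol genes, Insig1 (2.61 and 2.02) and Stard4 (2.17 and 2.09) were higher in Type I and Type III than in T09-treated EPSC, with list medians of 0.13 and 0.23. In the knockdown pair, 11 histone genes had a median of 0.46 (percentile 98.0 of matched random lists) and the 20 ribosomal protein genes 0.03, in the library where Rn45s took 0.683% of counts.

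Of the 13 genes raised by T09, 11 were above 0 and 7 over 2-fold higher in Type I than in Type III, Bmp4 (-0.56) and Trh (-1.87) being lower, and the median of Type III over untreated EPSC was 0.18 against 1.66 for Type I. In Type III, Mylip (3.42), Trh (2.20), Acsl3 (1.30), Scd1 (1.18) and Lpcat3 (1.04) were at least 2-fold above untreated EPSC. Scd2 (0.26) and Rnf145 (0.18) lay above untreated EPSC by less than 2-fold. Abca1 (-1.75), Acaca (-0.64), Bmp4 (-0.54), Fasn (-0.31), Abcg1 (-0.20) and Srebf1 (-0.07) lay below untreated EPSC. Mylip, Scd1 and Lpcat3 also lay 1.51, 1.12 and 1.29 above siNT, for which no agonist is listed, and Trh lay below it (-1.44). Neither reference is a day 5 blastoid. Mylip differed between them (1.83 CPM in EPSC, 7.04 in siNT), Scd1 and Lpcat3 less so (155 and 162, 52.8 and 44.5). These levels therefore do not decide whether the agonist was active. Across the 15 genes that passed for T09, the Type I over Type III ratio followed the T09 effect (Spearman 0.832, Pearson 0.774), as a loss of agonist activity in Type III would give. Such a loss and a change in cell makeup cannot be told apart, since no day 5 blastoid without agonist was sequenced. The 13 raised genes had a Type I over Type III median of 1.15. No cell type list reached that median, the largest being 0.46, for primitive endoderm genes. Outside the 15 genes, 77 genes with at least 50 counts did reach it. The highest of those was at 2.74, below Abca1 (5.25) and Abcg1 (3.49). The labels give no agonist dose, duration or presence in the medium for either class, so it is not known that the Type III cells were exposed as the Type I cells were, and whether LXR activity shapes the class of blastoid was not tested.

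LXR targets did not follow the knockdown: the 13 genes raised by T09 had a median log2 ratio of 0.0588 for siNr1h2 over siNT, with an interquartile range of 0.12, against -0.51 for Nr1h2, and 5 of the 13 lay below 0. A fall in step with the receptor transcript is argued against by that median. For the 13 genes as a set, too few counts to see one are argued against by the median half-width of the counting intervals, 0.0774. Abca1, Abcg1 and Mylip had wider intervals (0.218 to 0.932, -0.284 to 0.554 and -0.565 to 0.0198). That of Mylip held -0.51, so for Mylip a fall in step is not argued against. The counting intervals of Abca1, Acaca, Fasn, Scd2 and Srebf1 lay wholly above 0, and those of Bmp4 and Trh wholly below. What stays open is a fall smaller than that of the receptor transcript, of which the siNr1h2 library kept 70.0% of the siNT level. Also open are a fall later than 48 hours and one hidden by the noise between 1 siNr1h2 and 1 siNT library. The design measures none of these. Whether a deeper knockdown would lower the targets was not tested. The 13 genes were picked by their response to agonist, and no agonist is listed for either library. Whether they depend on Nr1h2 without agonist is not known, so the median does not speak to the receptor's part under T09. The siNr1h2 library also had the lowest total count and the highest share of Rn45s, and no biological explanation was tested for either.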
